A study of Oryza sativa with 6 samples.

How the data were processed

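Per the labels' protocols, libraries were made from total RNA of rice panicles with a kit of the NEBNext Ultra RNA family and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, the authors used fastp 0.19.7, HISAT2 and DESeq2. The genome build, the gene annotation, the read counter and its strand setting are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. The deposited table gives raw counts per gene, per the file headers, for 3 CTB3-cr1 and 3 Nipponbare libraries. The deposited table also gives FPKM per library, which equalled the counts divided by gene length and by a library total, to within a relative deviation of 4.85e-08. That total differed from the sum of counts by a ratio of 0.944 to 1.02, so FPKM carries the same reads under another scaling. Group means on a normalised signal scale, log2 fold changes and p-values of the comparison are the authors' own, per the file headers.

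The table has 39369 lines. A broken entry leaves 2 of them without a gene identifier, and these were left out of library sizes and tests, at most 0.000478% of a library's counts. The 39367 remaining genes include 2524 loci outside the annotation, whose identifiers begin with the word used for newly assembled loci. Groups and replicate numbers came from the sample titles.

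The main test was edgeR 4.0.16 with R 4.3.3: filterByExpr, TMM factors, estimateDisp and the quasi-likelihood F test at the default of this version, with Benjamini-Hochberg adjustment over 25636 genes and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F and are approximate. CPM uses the TMM-scaled library sizes. Where a group had 0 counts, a fold was bounded against a floor of 3 counts over the group, and with 1 to 3 counts a ratio was given with a 95% exact (Clopper-Pearson) interval. Floors and intervals cover counting error only. Library totals of 14422565 to 16982031 counts limit what can be said of weakly expressed genes.

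Before the data were examined, 28 gene lists, the alternatives and the rule for named genes were fixed. List members were found by identifier or by words in the deposited names and descriptions, so some members are unrelated to the list's name. The search word for thionins also matched methionine and cystathionine enzymes, and the DREB1 list holds a corepressor that binds a CBF1 factor. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log CPM, with an estimated correlation and with fry as alternatives, adjusted over the 28 lists. Camera compares a list with other genes, while fry tests whether its genes move on balance one way.

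Named genes were the expressed CAMTA family, up to 10 rises and 10 falls past the threshold with at least 5 CPM in the higher group, no overlap between groups and a functional name, up to 4 called members of each list or else its most abundant member, and 4 fixed genes. Other genes named in the text were chosen after their values were seen, including those that passed only when adjusted over a list alone.

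Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), with a filter of FPKM above 1 in 3 libraries or none. Chosen after seeing the data were the newer quasi-likelihood method of edgeR and the pathogenesis list without the methionine and cystathionine names. The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. These counts were drawn from the means and sizes of these libraries and from the dispersions that edgeR estimated. Camera called the 1 shifted list of 25 genes and 0 of 20 unshifted ones. Each gene was drawn independently in these simulations, so they do not test camera on lists whose genes vary together. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 13.9.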

Results

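RNA from panicles of rice was sequenced in 6 libraries, 3 from the wild-type cultivar Nipponbare and 3 from CTB3-cr1, a line the labels describe as a knockdown of CTB3 and name as knockout in the table's column headings. All panicles were taken after 1 day of a cold treatment abbreviated CS-PT, whose meaning is not given in the sources used here. The labels call the 3 samples of each group biological replicates. Total gene counts ranged from 14422565 in Nipponbare replicate 2 to 16982031 in CTB3-cr1 replicate 3, and between 30298 and 30724 genes had at least 1 count in a library. Ribosomal RNA took between 0.0207% and 0.0408% of the counts, and the 10 most abundant genes took between 3.44% and 4.32%. Panicles without cold treatment were not analysed here, so each difference is one between genotypes in the cold and not a response to cold.

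CTB3 itself was not analysed here, because no source used here pairs that name with a gene identifier, and the labels were therefore not checked against the targeted gene. The 7 expressed members of the CAMTA family, which are calmodulin-binding transcription factors fixed in advance as related genes, did not differ between the genotypes. Whether CTB3 is itself among these 7 genes is not given in the sources used here. Their log2 fold changes ranged from -0.19 for Os04g0388500 to 0.13 for Os03g0388500, with adjusted p of 0.994 and 0.996 in edgeR's quasi-likelihood test. Os03g0191000 stood at 124.2 CPM ± 16.4 (SD, n = 3) in CTB3-cr1 and 124.4 CPM ± 14.6 (SD, n = 3) in Nipponbare.

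The comparison of CTB3-cr1 with Nipponbare asked which transcripts differ between these genotypes in cold-treated panicles. No other CTB3 line was among the samples. An effect of CTB3 therefore cannot be told apart from any other difference between the CTB3-cr1 line and Nipponbare. The clearest differences were genes transcribed in one genotype and almost silent in the other. Os12g0100100, annotated as RNA Binding Domain-Containing Protein 1 with a role in abiotic stress tolerance, had 736, 547 and 824 counts in the Nipponbare libraries and 1, 0 and 0 in the CTB3-cr1 libraries, a ratio of 2206 in favour of Nipponbare (95% exact counting interval 396 to 87186, adjusted p = 0.000291 in edgeR). It lies on chromosome 12 from 2682 to 5428. Os03g0115800, a conserved hypothetical protein on chromosome 3 from 887193 to 888623, went the other way, with 4840, 7893 and 4404 counts in CTB3-cr1 against 0, 2 and 0 in Nipponbare (ratio 8183, interval 2265 to 67573, edgeR adjusted p = 0.000901). Coordinates are those of the deposited table, whose genome build is not given in the sources used here.

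Of 25636 genes tested, 20 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 16 higher and 4 lower in CTB3-cr1, and each of the 20 differed by at least 2-fold. An unadjusted p under 0.05 was reached by 1347 genes, close to the share of 0.05 expected if no gene differed. The groups did not overlap in 10.5% of the tested genes, against 10% expected if libraries were grouped at random. Of the 20 called genes, 10 carry no functional description. Among the 10 with a name or domain description, 6 rose. Os04g0510000, similar to a protein named after a sequenced clone, had 212, 187 and 185 counts in CTB3-cr1 and none in Nipponbare, which makes it at least 186-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0114). Os01g0356951, similar to a floozy-type flavin monooxygenase, an enzyme class that includes auxin biosynthesis enzymes, reached 12.4 CPM ± 5.10 (SD, n = 3) against 0.105 CPM ± 0.133 (SD, n = 3), a log2 fold change of 6.75 ± 0.70 (SE). Os08g0496700, with a Myb/SANT-like domain, rose by 5.12 ± 0.53 (SE) on the log2 scale. The exocyst subunit gene Os09g0347300 of the EXO70 family, whose products tether secretory vesicles, rose by 4.39 ± 0.49 (SE) from a level of 0.312 CPM. An unannotated locus on chromosome 10 from 15271488 to 15277135, with BTB/POZ and Myb/SANT-like domains, rose by 2.68 ± 0.26 (SE). Os02g0706500, an AAA-type ATPase on chromosome 2 from 29199147 to 29204307, was the most abundant of these 6, at 113.7 CPM ± 27.2 (SD, n = 3) against 21.9 CPM ± 2.00 (SD, n = 3), a log2 fold change of 2.37 ± 0.20 (SE) with an edgeR adjusted p of 0.0201.

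Besides Os12g0100100, 3 genes with a name or domain description fell. The ZIP transporter gene Os08g0100200, whose family moves zinc and iron across membranes, stood at 1.27 CPM ± 0.699 (SD, n = 3) in CTB3-cr1 and 14.2 CPM ± 2.04 (SD, n = 3) in Nipponbare, a log2 fold change of -3.49 ± 0.37 (SE) with an edgeR adjusted p of 0.0397. An unannotated locus on chromosome 4 from 17065888 to 17071538, with a helitron helicase-like domain of the kind found in rolling-circle transposons, had a log2 fold change of -2.70 ± 0.29 (SE). The fourth gene that fell, an unannotated locus on chromosome 12 from 1001 to 2663, has a zinc-binding reverse transcriptase domain and had 50, 49 and 49 counts in Nipponbare and none in CTB3-cr1, at least 51.7-fold lower against the floor of 3 counts over the group. It was named after its values were seen, as were the genes of the next sentence. Of the 10 called genes without any functional description, the locus on chromosome 12 from 19586760 to 19587749 had 1160, 1872 and 1587 counts in CTB3-cr1 and 0 in each Nipponbare library (at least 1470.4-fold higher), while Os07g0511400 and Os03g0299700 were expressed in both genotypes. Os07g0511400 reached 157 CPM against 6.51 CPM and Os03g0299700 194 CPM against 9.76 CPM. Leaving out single libraries lowered the number of called genes to 6, 4 and 5 without CTB3-cr1 replicate 1, 2 and 3, and to 6, 7 and 16 without Nipponbare replicate 1, 2 and 3.

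**Figure D1:**
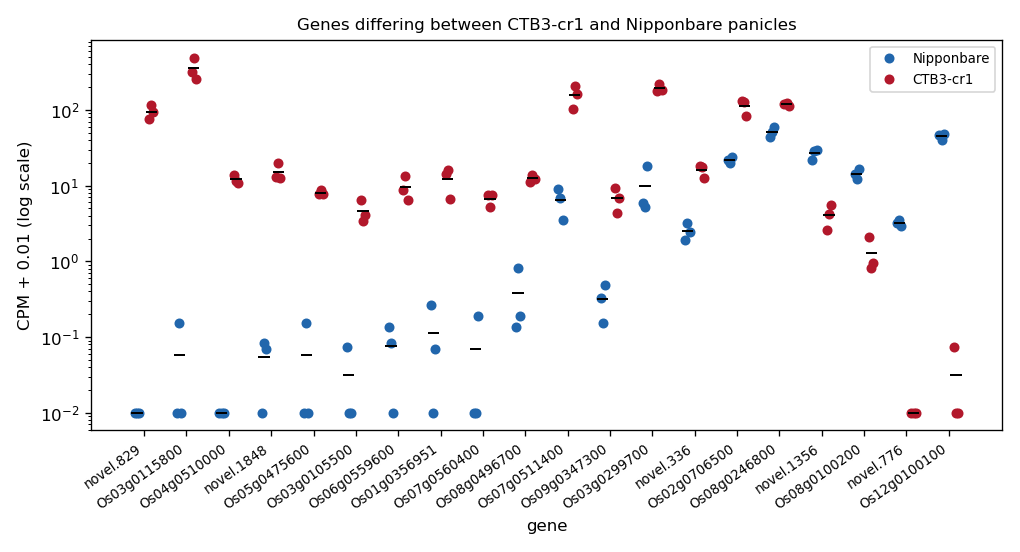
CPM with 0.01 added, on a log axis, of the 20 genes past the adjusted p threshold in edgeR, ordered by log2 fold change, with 1 point per library, 3 per genotype, and a bar at the mean. The groups do not overlap in any of these genes, and the lowest points at 0.01 are libraries without a count.

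The authors' deposited table calls 202 genes at an adjusted p under 0.05, 69 higher and 133 lower in CTB3-cr1, so its balance of directions is the opposite of that in edgeR. A rerun of DESeq2 on the same counts also called 202, and 202 were shared with the authors' deposited table. All 20 genes called by edgeR are among them. Of the 196 that were also tested in edgeR, 196 had the same sign there. In counts simulated from these libraries for this comparison over 25636 genes, edgeR recovered 79% of genes changed 4-fold and 13% of those changed 2-fold, with 7 false calls among 99, and DESeq2 recovered 94% and 52%, with 66 false calls among 212.

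Genes of the tapetum and pollen wall passed the set test camera as lower in CTB3-cr1, but only at its preset correlation between genes. The tapetum is the inner anther layer that feeds developing pollen and supplies its wall. Of the 21 tested members of this list, 15 had a negative and 6 a positive log2 fold change, with a median of -0.34, and camera gave an adjusted p of 0.00172 with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.707, the set test fry gave an adjusted p of 0.549, and 0 members passed over all genes tested in edgeR, where 1347 genes had an unadjusted p under 0.05, while 4 members are lower in the authors' deposited table. Adjusted over the list alone, 5 members fell and 0 rose. They were RAFTIN1 (Os08g0496800), an anther protein gene, with a log2 fold change of -2.06 ± 0.38 (SE), ETERNAL TAPETUM 1 (Os04g0599300), a transcription factor of tapetal cell death, with -1.52 ± 0.35 (SE), CYSTEINE PROTEASE 1 (Os04g0670500) with -2.07 ± 0.58 (SE), polyketide synthase 1 (Os10g0484800), which makes pollen wall precursors, at 573 CPM ± 119 (SD, n = 3) against 1144 CPM ± 212 (SD, n = 3), and the cytochrome P450 gene 703A3 (Os08g0131100) with -0.74 ± 0.22 (SE). Members on the positive side included TPD1-like 1A (Os12g0472500), a regulator of early anther cell differentiation, with 0.59 ± 0.30 (SE), and TDR INTERACTING PROTEIN2 (Os01g0293100) with 0.52 ± 0.37 (SE), neither of which passed, while MULTIPLE SPOROCYTE 1 (Os01g0917500) had 0.04 ± 0.24 (SE) and UNDEVELOPED TAPETUM 1 (Os07g0549600) -0.07 ± 0.19 (SE). Nipponbare replicate 2, which lay apart from the other 5 libraries on the first principal component (score 80.3, against -54.8 to 17.2), had the highest level of RAFTIN1 and ETERNAL TAPETUM 1. That component took 38.9% of the variance. CTB3-cr1 replicates 1, 2 and 3 scored -54.8, 3.58 and -42.3 on it, and Nipponbare replicates 1, 2 and 3 scored 17.2, 80.3 and -4.02. The genotypes thus overlapped there, although the CTB3-cr1 libraries tended to score lower. On the second component Nipponbare replicate 3 had the highest score (67.1, against -43.0 to 20.9). Without Nipponbare replicate 2 the list still passed camera (adjusted p = 0.000619, median -0.25). The set test lost its call without CTB3-cr1 replicate 1 (median -0.32, adjusted p = 0.138) and without Nipponbare replicate 1 (median -0.40, adjusted p = 0.123). The median was -0.62 without CTB3-cr1 replicate 2.

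**Figure D2:**
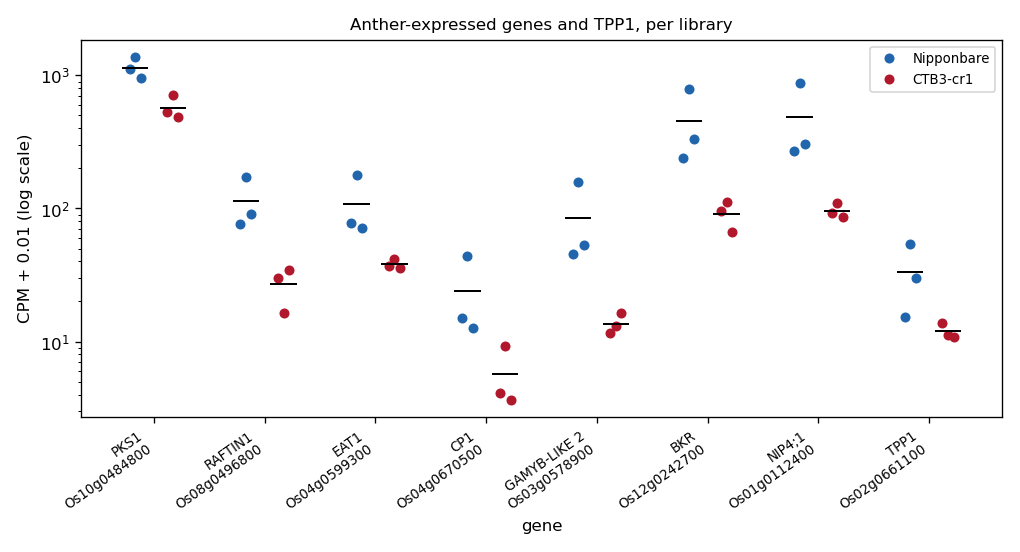
CPM with 0.01 added, on a log axis, of 7 genes plotted as anther-expressed and of trehalose-6-phosphate phosphatase TPP1, with 1 point per library, 3 per genotype, and a bar at the mean. The descriptions of GAMYB-LIKE 2, BETA KETOACYL REDUCTASE and Os01g0112400 do not mention the anther. Except for polyketide synthase 1 and TPP1, the genes were named only after their values were seen. Members of the tapetum list with a positive log2 fold change are not plotted. Nipponbare replicate 2 had the highest level of each gene. RAFTIN1 averaged 27.0 CPM in CTB3-cr1 and 113 CPM in Nipponbare, and none of the 8 genes passed the adjusted p threshold over all genes in edgeR. Their adjusted p in the authors' deposited table lies between 8.47e-07 for GAMYB-LIKE 2 and 0.0444 for TPP1.

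Histone and cell cycle genes passed camera as higher in CTB3-cr1, again only at the preset correlation. Of 118 tested members, 87 had a positive and 31 a negative log2 fold change, with a median of 0.13 and a camera adjusted p of 0.00172, which became an adjusted p of 0.707 with an estimated correlation and an adjusted p of 0.726 with fry. Over all genes 0 members passed in edgeR. Adjusted over the list alone 1 member rose, the histone H2A gene Os01g0974600, with a log2 fold change of 3.00 ± 0.49 (SE). The most abundant member, the histone H2A gene Os05g0461400, had 0.15 ± 0.12 (SE). This call was lost without Nipponbare replicate 2, where the adjusted p was 0.625 and the median 0.04, and without CTB3-cr1 replicate 1 (median 0.07, adjusted p = 0.230). It was also lost without CTB3-cr1 replicate 3 (adjusted p = 0.0512), where the median stayed at 0.13. The median was 0.23 without CTB3-cr1 replicate 2 and 0.33 without Nipponbare replicate 3.

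With all 6 libraries and genotype alone in the model, none of the other reproductive lists passed camera on log CPM. Meiosis genes had a median log2 fold change of 0.15 over 33 tested genes (camera adjusted p = 0.162), and passed without CTB3-cr1 replicate 2 (adjusted p = 0.0121) and without Nipponbare replicate 3 (adjusted p = 0.0254). Their median shrank to 0.05 without CTB3-cr1 replicate 3 (adjusted p = 0.783) and to 0.07 without Nipponbare replicate 2 (adjusted p = 0.629). Their most abundant member, ANTHER SPECIFIC PROTEIN 6 (Os11g0582500), matched through its description as a post-meiotic lipid transfer protein and had -2.63 ± 0.84 (SE). Pollen genes had a median of 0.04 over 94 genes (adjusted p = 0.778), and adjusted over the list alone 1 of them fell, Os04g0573100, a glucose-methanol-choline oxidoreductase of cutin synthesis and anther development, with -1.41 ± 0.24 (SE). MADS-box floral factors had a median of 0.02 over 37 genes (adjusted p = 0.371), with RICE APETALA 1A (Os07g0108900) at 0.15 ± 0.12 (SE). Lipid transfer proteins had a median of -0.25 over 69 genes and an adjusted p of 0.0509. Their median ranged from -0.03 without CTB3-cr1 replicate 1 to -0.50 without CTB3-cr1 replicate 2, and was -0.04 without Nipponbare replicate 2. They passed without CTB3-cr1 replicate 2 (adjusted p = 0.00139), without CTB3-cr1 replicate 3 (0.0149 as adjusted p), without Nipponbare replicate 3 (0.000135 as adjusted p), with the replicate block (0.0318 as adjusted p) and on FPKM with pseudocount 1 (0.0150 as adjusted p). With all 6 libraries and an estimated correlation the lipid transfer list had an adjusted p of 0.707, as did the meiosis list, and fry gave both an adjusted p of 0.726.

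No gene of sugar supply passed over all genes in edgeR. Among 77 tested genes of sugar transport and sucrose cleavage the median was -0.08 (camera adjusted p = 0.163). The list passed without CTB3-cr1 replicate 2 (median -0.15, adjusted p = 0.0157) and without Nipponbare replicate 3 (median -0.17, adjusted p = 0.00701), while the median shrank to -0.03 without Nipponbare replicate 2 (adjusted p = 0.625). With an estimated correlation its adjusted p was 0.749. Adjusted over the list alone, SUCROSE TRANSPORTER 1 (Os03g0170900) rose, from 13.0 CPM ± 2.40 (SD, n = 3) in Nipponbare to 38.4 CPM ± 8.19 (SD, n = 3) in CTB3-cr1, while SWEET15 (Os02g0513100), a sugar efflux carrier, and the sugar transporter gene Os05g0169700 fell, with log2 fold changes of -1.73 ± 0.32 (SE) and -2.17 ± 0.44 (SE). Over all genes SUCROSE TRANSPORTER 1 had an edgeR adjusted p of 0.0779. The authors' deposited table gives SUCROSE TRANSPORTER 1 an adjusted p of 4.16e-08 and SWEET15 one of 5.08e-05. Trehalose metabolism, with 17 tested genes, had a median of -0.12 (adjusted p = 0.203), which turned to 0.03 without Nipponbare replicate 3 (adjusted p = 0.607). Within it the trehalose-6-phosphate phosphatase gene TPP1 (Os02g0661100), fixed in advance, stood at 11.9 CPM ± 1.59 (SD, n = 3) in CTB3-cr1 and 33.2 CPM ± 19.7 (SD, n = 3) in Nipponbare, a log2 fold change of -1.48 ± 0.41 (SE) that did not pass in edgeR (adjusted p = 0.714). In the authors' deposited table its adjusted p is 0.0444. Starch metabolism had a median of 0.00 over 59 genes (adjusted p = 0.469), and ENDOSPERM STORAGE PROTEIN 2 (Os11g0199200), which the seed storage list also holds, had -0.05 ± 0.16 (SE). Seed storage proteins had a median of 0.04 over 14 genes (adjusted p = 0.821).

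Cold regulators did not separate the genotypes. The 8 tested genes of the DREB1 and cold regulator list had a median of 0.04 (camera adjusted p = 0.397), and the most abundant of them, Os11g0523700, similar to ICE1, had 0.35 ± 0.25 (SE). DREB1A, DREB1B and DREB1C, cold-induced transcription factors, lay below the expression filter, with 7, 3 and 16 counts summed over the CTB3-cr1 libraries and 2, 9 and 22 over the Nipponbare libraries. Tested without the filter, among 33504 genes, they had log2 fold changes of 1.61 ± 1.24 (SE), -1.56 ± 1.14 (SE) and -0.52 ± 0.66 (SE), and none passed in edgeR (adjusted p = 0.927, 0.927 and 0.949). All 18 genes of the list entered that test, with a median of -0.03 (camera adjusted p = 0.665). Cold tolerance loci (11 genes, median -0.06, adjusted p = 0.821), late embryogenesis, dehydrin and cold-regulated proteins (34 genes, median 0.07, adjusted p = 0.469), heat shock proteins (130 genes, median -0.02, adjusted p = 0.469), antioxidant enzymes (84 genes, median 0.01, adjusted p = 0.874) and calcium signalling genes (251 genes, median -0.01, adjusted p = 0.821) did not pass camera. The circadian clock genes had 8 of 9 members above 0, with a median of 0.10 (adjusted p = 0.206), and GIGANTEA (Os01g0182600) had 0.22 ± 0.17 (SE).

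No gene of the hormone lists passed over all genes in edgeR, and 3 passed when adjusted over a list alone. ABA-8'-HYDROXYLASE 2 (Os08g0472800), which breaks down abscisic acid, rose when adjusted over the list alone, with a log2 fold change of 1.07 ± 0.13 (SE), and had an adjusted p of 0.0565 over all genes in edgeR. The abscisic acid list as a whole had a median of 0.04 over 75 genes (camera adjusted p = 0.251). Among 48 gibberellin genes (median 0.03, adjusted p = 0.821), GIBBERELLIN 2-OXIDASE 9 (Os02g0630300), an enzyme that inactivates gibberellin, rose and GAMYB-LIKE 2 (Os03g0578900) fell. Their log2 fold changes were 1.06 ± 0.20 (SE) and -2.65 ± 0.49 (SE), and in edgeR both passed only when adjusted over the list alone. GAMYB-LIKE 2 stood at 157 CPM in Nipponbare replicate 2, 45.6 and 53.2 in the other Nipponbare libraries, and a mean of 13.6 in CTB3-cr1. The authors' deposited adjusted p is 8.4e-08 for ABA-8'-HYDROXYLASE 2, 0.00338 for GIBBERELLIN 2-OXIDASE 9 and 8.47e-07 for GAMYB-LIKE 2. Jasmonate genes (47, median -0.03, adjusted p = 0.203) and auxin genes (158, median -0.03, adjusted p = 0.748) had no member that passed either way. The auxin list does not hold the called gene Os01g0356951, since the words of its description were not among the search words. That gene, similar to a floozy-type flavin monooxygenase, rose with an edgeR adjusted p of 0.0397.

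Among defence and housekeeping lists, none passed camera on log CPM with all 6 libraries. NB-LRR proteins had a median of -0.10 over 224 genes (camera adjusted p = 0.0771), WRKY factors -0.17 over 67 (0.206 as adjusted p), and pathogenesis-related and phytoalexin genes -0.03 over 149 (adjusted p = 0.203). Without the methionine and cystathionine names, this last list kept 82 tested genes, with a median of -0.08 and a camera adjusted p of 0.0617. CLASS I CHITINASE (Os05g0399700) was the most abundant of the last list, at 743 CPM in CTB3-cr1 and 1535 CPM in Nipponbare, with -1.05 ± 0.24 (SE) and an edgeR adjusted p of 0.492. Its adjusted p in the authors' deposited table is 0.00184. NB-LRR proteins passed without Nipponbare replicate 1 (adjusted p = 0.0329) and on FPKM with pseudocount 1 (adjusted p = 0.0270), and WRKY factors without CTB3-cr1 replicate 2 (adjusted p = 0.0267). The WRKY median was 0.00 without Nipponbare replicate 3 (adjusted p = 0.988). With an estimated correlation both lists had an adjusted p of 0.707. Photosynthesis genes had a median of -0.21 over 58 genes (adjusted p = 0.163). Their direction turned without Nipponbare replicate 2 (median 0.05, adjusted p = 0.328), and they passed as lower without CTB3-cr1 replicate 2 (adjusted p = 0.0131), without Nipponbare replicate 1 (adjusted p = 0.0329) and without Nipponbare replicate 3 (adjusted p = 0.0352). The remaining lists were cell wall genes, with a median of -0.10 over 147 (adjusted p = 0.206), and cytosolic ribosomal protein genes, 0.00 over 255 (adjusted p = 0.907). Cell wall genes passed without CTB3-cr1 replicate 2 (adjusted p = 0.0121) and without Nipponbare replicate 3 (adjusted p = 0.00701), but their median was 0.00 without CTB3-cr1 replicate 1 (adjusted p = 0.809), where camera pointed up, and -0.02 without Nipponbare replicate 2 (adjusted p = 0.625). Photosynthesis and cell wall genes both had an adjusted p of 0.875 with an estimated correlation. Ribosomal protein genes passed in opposite directions without CTB3-cr1 replicate 1 (median -0.16, adjusted p = 0.000150) and without CTB3-cr1 replicate 2 (median 0.13, adjusted p = 5.01e-05). With all 6 libraries and an estimated correlation their camera adjusted p was 0.985. The medians and the means of the lists differed in sign for starch metabolism and for late embryogenesis proteins, gibberellin, pollen, MADS-box, ribosomal and seed storage genes. For these last 6 lists camera pointed up, and the means were -0.02, -0.05, -0.03, -0.03, -0.01 and -0.05.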

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

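The newer edgeR method and the shortened pathogenesis list were tried only after the data were seen. DESeq2 called 202 genes, 69 higher, 133 lower and 186 changed at least 2-fold, against 20, 16, 4 and 20 in edgeR. The simulated data gave DESeq2 the larger share of false calls. They were drawn with the dispersions of edgeR, so they do not rank the 2 tools on the real counts. The cause of the difference in the real counts was not tested. Without a filter 25 genes were higher. With the replicate block 4 genes were called, 3 higher, 1 lower and 4 at least 2-fold. The numbers showed no clear pairing of the samples. Deviations of same-numbered libraries from their group means correlated at -0.27, 0.37 and -0.07 across genes, and not every library correlated best with its own number. The highest value between genotypes was 0.47, for CTB3-cr1 replicate 1 and Nipponbare replicate 3. Deviations within a group of 3 depend on each other, so these values cannot exclude pairing or a shared batch. Leaving out 1 library at a time gave 4 to 16 called genes, 3 to 14 higher, 1 to 2 lower and 4 to 16 at least 2-fold, from fewer samples; the fewest came without CTB3-cr1 replicate 2. Os12g0100100, Os03g0115800 and the unannotated loci on chromosome 12 at 19586760 and chromosome 6 at 9409135 passed in all 18 alternatives. The other counts, including 26 calls with the newer method of edgeR, stayed within 1.5 times. Of the 28 lists, 2 passed camera, 0 with an estimated correlation, 0 with fry, 4 on FPKM with pseudocount 1, and 1 to 9 when single libraries were left out, 9 without CTB3-cr1 replicate 2, 7 without Nipponbare replicate 3, and 1 without CTB3-cr1 replicate 1 or without Nipponbare replicate 2. The cause was not tested. Cytosolic ribosomal proteins reversed, from a median of 0.00 to -0.16 without CTB3-cr1 replicate 1, and had 0.13 without CTB3-cr1 replicate 2. They passed camera without either library. Photosynthesis genes turned from a median of -0.21 with all libraries to 0.05 without Nipponbare replicate 2, and passed in neither setting. Without 1 library the medians of several other lists, such as cell wall and WRKY genes, also changed sign, short of the threshold. Under the block, lipid transfer proteins also passed (adjusted p = 0.0318). Depth limits weak genes such as DREB1A, with 7 and 2 counts per group.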

Other observations

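The tests of a single Nipponbare library, of the panicle stage, of segments from another parent, of unannotated loci and of the chromosome ends were chosen after the results they bear on had been seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 20 called genes, 20 at least 2-fold and 2 gene lists, the highest of the other splits gave 8, 8 and 8, and 1, 1 and 9 of the 10 splits gave at least as many. With an estimated correlation or with fry, no list passed in any of the 10 splits. A list that passes camera at the preset correlation is therefore not tied to the genotype by that alone, and why other splits moved more lists is open.

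Other genes, named after their values were seen, included A-TYPE RESPONSE REGULATOR 3 (Os02g0830200), a cytokinin signalling gene, at 15.6 CPM in CTB3-cr1 and 5.17 CPM in Nipponbare (log2 fold change 1.59 ± 0.23 SE, edgeR adjusted p = 0.119). BETA KETOACYL REDUCTASE (Os12g0242700) and the NOD26-like intrinsic protein Os01g0112400 had log2 fold changes of -2.32 ± 0.46 (SE) and -2.33 ± 0.45 (SE), with edgeR adjusted p of 0.365 and 0.345. The authors' deposited adjusted p is 7.93e-07 for A-TYPE RESPONSE REGULATOR 3, 7.07e-06 for BETA KETOACYL REDUCTASE and 4.72e-06 for Os01g0112400. Nipponbare replicate 2 held the highest levels of BETA KETOACYL REDUCTASE and Os01g0112400. BETA KETOACYL REDUCTASE had 795 CPM there, against 238 and 331 in the other Nipponbare libraries and a mean of 91.1 in CTB3-cr1. Os01g0112400 had 878 CPM there, against 271 and 307, and a mean of 96.2 in CTB3-cr1. Of 197 protein domain families with at least 10 tested genes, 8 passed camera, 7 lower and 1 higher in CTB3-cr1, and 0 with an estimated correlation. The UDP-glycosyltransferases (84 genes, median log2 fold change -0.22) had the lowest camera adjusted p, 0.00449, and the 1 higher family, proteins with a cyclin C-terminal domain (28 genes), had a median of 0.17 and a camera adjusted p of 0.0196. The NB-ARC family (251 genes, median -0.13), the domain of NB-LRR proteins, passed at an adjusted p of 0.0285 (0.938 with an estimated correlation), while the NB-LRR list did not.

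The tapetum result may reflect the CTB3 genotype, another difference of the CTB3-cr1 line, a difference in panicle stage, 1 library or the preset correlation of the test. These cannot be told apart with a single CTB3 line and 3 libraries per group. Without Nipponbare replicate 2 the list still passed camera at the preset correlation (adjusted p = 0.000619). Lists also passed that test in other splits of the libraries, so the pass cannot decide whether that library alone is the source. The tapetum median of -0.25 lay between the bounds set for and against that source, and the call is lost with an estimated correlation. If CTB3-cr1 panicles held less anther tissue, the meiosis genes should fall too, but the tapetum median lay 0.47 below theirs once the 2 genes in both lists were left out (medians -0.32 over 19 and 0.15 over 31 genes, difference -0.47, 95% bootstrap interval over genes -1.16 to -0.12), short of the bound of 0.5 set in advance. That interval treats genes as independent and leaves out the variation between libraries. The main axis of variation within groups correlated with the fold change at an absolute r of 0.19 across genes, which are not independent replicates, and other splits reached 0.40, so that test leaves stage open. The CTB3 genotype remains open and untested against these.

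A set of 19 genes had at most 5 counts in every library of one genotype and at least 30 in every library of the other, 17 of them expressed in CTB3-cr1 and 2 in Nipponbare. Of the 17, 15 were outside the annotation or hypothetical, against 5191 of 20887 other genes expressed in CTB3-cr1 (odds ratio 22.7, 95% interval 5.27 to 204, Fisher's exact p = 6.93e-08). This does not show that unannotated or repeat-like loci became active in the line, since loci silent in Nipponbare may lack annotation through that silence alone. The loci silent in CTB3-cr1, of which 1 of 2 was unannotated, are too few to compare (Fisher's exact p = 0.298), so this stays open. This comparison replaced an earlier one that pooled both directions, and whose result had been seen. Segments from another parent would place such genes together, and 2 of them had another within 500 kb, the pair at the end of chromosome 12, which 43.1% of 10000 random draws matched. That leaves small segments open.

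That pair, the unannotated locus from 1001 to 2663 and Os12g0100100, comprises the first 2 tested genes of chromosome 12, and the first 2 tested genes of chromosome 11, Os11g0100100 (1180 to 4230, an autophagy gene) and Os11g0100200 (4400 to 7050, similar to ALY), had log2 fold changes of 0.94 ± 0.21 (SE) and 1.08 ± 0.16 (SE), with edgeR adjusted p of 0.492 and 0.126. For Os11g0100100 and Os11g0100200 the authors' deposited adjusted p is 0.0245 and 2.33e-05. The next tested genes, Os12g0101000 and Os11g0101200, had 0.18 ± 0.28 (SE) and 0.44 ± 0.29 (SE). The mean of the first 2 chromosome 11 genes was 1.01, near the value of 1 that an extra copy of the chromosome 11 end in place of the chromosome 12 end would give, so such an exchange may underlie both changes, as a hypothesis found and tested on the same genes. Reads moving between similar copies would leave the sum of Os11g0100200 and Os12g0100100 level, if the 2 are such copies and shared reads were counted. Neither condition is shown here, since the sequences were not compared and the read counter is not given. The descriptions of the 2 genes are worded differently, which does not settle whether they are copies. The next tested genes, Os12g0101000 and Os11g0101200, share a description (similar to an RNase P subunit p30 family protein), so similar ends are possible. The sum had a log2 ratio of -0.94 ± 0.16 (SE), from 59.7 CPM in Nipponbare to 31.0 CPM in CTB3-cr1. That argues against moved reads only under those 2 conditions. DNA of the line was not analysed here.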
